A study of Rattus norvegicus with 12 samples.

How the data were processed

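RNA of 12 rat tissue samples was measured on 12 single-colour Affymetrix Rat 230 2.0 arrays, 3 for each of 4 groups. Per the labels' protocols, male adult Sprague-Dawley rats received 70 mg/kg diethylnitrosamine (DEN) by intraperitoneal injection once per week for 10 weeks, and controls received distilled water. Rats were killed at the end of week 5 (hepatitis), weeks 13 to 14 (cirrhosis) and weeks 23 to 24 (hepatocellular carcinoma, HCC) after DEN treatment. The time of sacrifice of the controls, scan dates and batches are not given in the sources used here. The series description speaks of liver tissue for the first 3 groups and of HCC tissue for the last, while the tissue label says liver for all 12. Total RNA was isolated with TRIzol and labelled with biotin by the manufacturer's standard protocol, per the labels. The groups are those of the labels, and the replicate number is the one in the sample title.

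The deposited values were linear intensities, 1 per probe set and array, as the authors gave them, and not on a log scale. Quartiles were nearly equal on the 12 arrays, and the step that made them so is not given in the sources used here. The submitters' processing notes name MAS5 and RMA, whose role, order and versions are not given in the sources used here, and do not state which made the values. Median intensity was 28.69 to 30.94 per array, and 33.9% to 35.8% of values lay under 16. An array gives no count of molecules, so the number of arrays limits the precision. All 12 columns of values were used, and 0 were left out.

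The table held 31099 probe sets, 57 of them array controls. Probe sets were named from the platform's annotation of the series, with symbols updated from RefSeq genes of the GRCr8 assembly, of which no coordinates were used. Of the probe sets 20826 had 1 gene, 436 several genes and 9780 none. The update changed 1 probe set's symbol, and 66 symbols were not found and kept as annotated. For each of 14217 genes the probe set with the highest mean over the 12 arrays was tested, and 4525 genes had several. In a fit of all probe sets no named gene had a probe set called in the opposite direction. In that fit no probe set of Timp2, Mvk and Cux2 in hepatitis, nor of Gpc3 and Cdkn1a in HCC against control, was past the threshold, and of Igf2 in HCC 1 of 4 was.

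Values were analysed as log2(value + 16). The added 16 damps noise of dim probe sets, so that fold changes of genes with low intensity are understated. Gene tests used limma 3.58.1 (lmFit, eBayes) in R 4.3.3 on all 12 arrays, with 5 contrasts: hepatitis, cirrhosis and HCC each against control, cirrhosis against hepatitis, and HCC against cirrhosis. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes, in 2-sided moderated tests. Errors beside a log2 difference are its standard error in that fit, and errors beside an intensity are the standard deviation. A moderated F test asked which genes differed in any stage. The prior degrees of freedom were 1.8. The fit takes 1 spread per gene from all 12 arrays. The median SD per gene was 0.0856 in control, 0.104 in hepatitis, 0.0724 in cirrhosis and 0.207 in HCC. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

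The groups, contrasts, tests, threshold, gene lists, rule for named genes and a set of other settings were fixed before the data were examined. Named genes are, in each comparison, the 5 with the largest rise and the 5 with the largest fall among called genes whose 3 arrays of 1 group all lie above or below the 3 of the other, passing over unnamed loci and probe sets of several genes. Up to 4 called members of each list described are added, in order of absolute log2 change, or the member with the smallest adjusted p where none is called. In comparisons with control 12 marker genes are given whatever their test says. Genes outside this rule are said to be chosen after their values were seen.

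The 37 lists were extracellular matrix, stellate cells and myofibroblasts, cholangiocytes and ductular cells, macrophages and Kupffer cells, T and NK cells, B and plasma cells, neutrophils and mast cells, sinusoidal endothelium, vascular endothelium, erythroid cells and blood, pancreatic acinar cells, skeletal muscle, adipocytes, cell proliferation, p53 targets, NRF2 and phase II enzymes, oncofetal and HCC markers, hepatocyte plasma proteins, liver transcription factors, male-biased and female-biased liver genes, xenobiotic P450 and oxidases, bile acid synthesis and transport, urea cycle and amino acid catabolism, fatty acid oxidation, cholesterol synthesis, fatty acid synthesis, glycolysis and glucose uptake, gluconeogenesis and glycogen, pericentral and Wnt targets, acute phase proteins, interferon response, MHC class II, cytokines and chemokines, unfolded protein response, immediate early genes and circadian clock. They hold 7 to 38 measured genes each, and at most 4 members of a list also stood in another. Each list was tested in each contrast by limma's camera with a preset correlation of 0.01, which compares a list with all other genes, adjusted over the 185 tests. Of these 76 were called, 30 up and 46 down. With a correlation estimated for each list 0 were called by camera, 21 had an unadjusted p under 0.05, and fry, which asks whether a list's genes moved one way, called 54. Median, mean and test had the same sign in every called list.

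Overlaps between stages were compared with the product of the numbers called over the genes tested, and with 50 simulations of unchanged groups against the same controls. RNA quality was measured as the difference in log2 value between the 3' and 5' control probe sets of Gapdh and of beta actin. The settings fixed beforehand were quantile normalization, leaving out the dimmest 30% of genes, the mean of a gene's probe sets, all probe sets one by one, a trended robust variance prior, the replicate number as a block, array weights, a 2-fold minimum, an adjusted p under 0.01, log2(value + 1), only the 2 groups compared, and each array left out in turn. Added after seeing the data were fits without the HCC arrays, with the 3 cirrhosis arrays averaged to 1, and with the Gapdh difference as a covariate.

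The procedure was tested on simulated data with the measured spread of each group, in which 100 of the brighter genes changed by 1 and 100 by 2 on the log2 scale. It recovered 76% and 93% of these in hepatitis against control, 78% and 94% in cirrhosis against control, and 80% and 95% in HCC against control. In cirrhosis against hepatitis it recovered 65% and 92%, and in HCC against cirrhosis 73% and 95%. Unchanged genes called were 31, 22, 239, 19 and 241 in that order of comparisons. In both comparisons with HCC the unchanged genes called outnumbered the changed genes recovered, and in the other comparisons they did not. The threshold thus did not hold false calls to its nominal rate in the simulated data, least of all for HCC. The share of false calls among the measured HCC calls is not known.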

Results

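Gene expression was measured in 12 rat tissue samples, 3 per group, on single-colour Rat 230 2.0 arrays. The groups were control liver of rats injected with distilled water, liver at the hepatitis stage, liver at the cirrhosis stage and hepatocellular carcinoma (HCC) tissue. The carcinogen was diethylnitrosamine (DEN), an alkylating agent that is activated in hepatocytes. The labels give sacrifice at week 5 for hepatitis, weeks 13 to 14 for cirrhosis and weeks 23 to 24 for HCC, counted from the DEN treatment without saying from its start or end, and no time for the controls. Median intensity lay between 28.69 and 30.94 on the 12 arrays, and 33.9% to 35.8% of an array's values were under 16. The number of arrays, 3 per group, limits the precision of every value. The labels do not say that each array is a separate rat, so p-values measure only the spread between these samples.

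The HCC arrays stood apart from the other 9. The first principal component held 60.3% of the variance and the second 13%. HCC replicates 1 and 3 lay at 73.1 and 75.4 on the first, and HCC replicate 2 at 32.4. Alpha-fetoprotein (Afp), a fetal liver protein and HCC marker, had an intensity of 576.5 on HCC replicate 2 against 9199 and 7098 on replicates 1 and 3. Correlations between replicates, taken across genes, were 0.996 to 0.997 in cirrhosis, 0.988 to 0.992 in control, 0.984 to 0.988 in hepatitis and 0.937 to 0.959 in HCC. The HCC arrays also had the largest differences between the 3' and 5' control probe sets of Gapdh, at 2.31 ± 0.9 (log2, SD, n = 3), with 1.35, 2.43 and 3.14 on replicates 1, 2 and 3. That difference was 0.93 ± 0.08 in control, 0.52 ± 0.16 in hepatitis and 0.49 ± 0.07 in cirrhosis. For beta actin it was 3.82 to 4.85 in HCC and 2.14 to 2.69 on the other arrays.

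**Figure D1:**
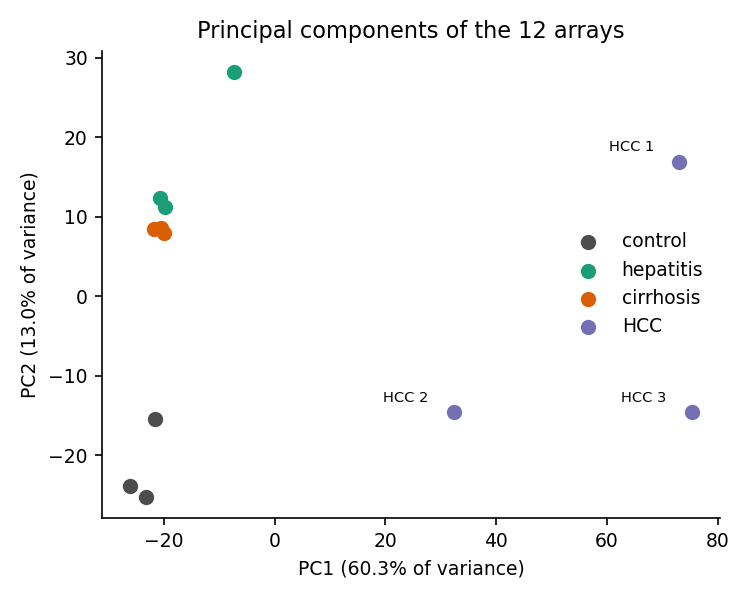
Each point is 1 of the 12 arrays, placed by its first and second principal components and coloured by group. HCC replicate 2 lies at 32.4 on the first component, and the other HCC arrays at 73.1 and 75.4.

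**Figure D2:**
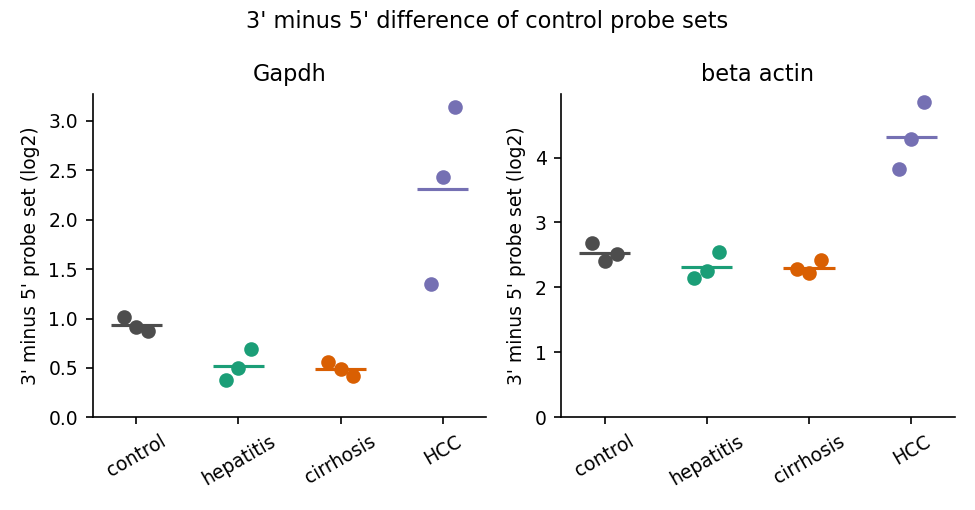
Points show the 3' minus 5' log2 difference of the Gapdh and beta actin control probe sets on each array, and horizontal lines the group means. All HCC values for Gapdh, 1.35 to 3.14, lie above the control mean of 0.93.

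The first comparison asked what had changed at the hepatitis stage. Of 20 measured targets of p53, the transcription factor activated by DNA damage, 8 rose and 1 fell (adjusted p = 0.43 with an estimated correlation). Among them the cell cycle inhibitor Cdkn1a rose by 3.53 ± 0.31 (log2, SE, n = 3 per group; limma adjusted p = 0.000569). Phgdh and Psat1, enzymes of serine synthesis, and asparagine synthetase (Asns) were among the largest falls. Of 16 fatty acid synthesis genes 6 fell, and of 18 cholesterol synthesis genes 4 fell (adjusted p = 0.43 and 0.438 with an estimated correlation). In limma's moderated test 266 genes were higher and 302 lower in hepatitis than in control, and 92 and 88 of these changed at least 2-fold.

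Adam8, a membrane metalloprotease, had the largest rise at 5.63 ± 0.26 (adjusted p = 1.01e-05), from an intensity of 20.6 ± 1.88 to 1850 ± 589 (SD, n = 3; limma test). Mybl1, a transcription factor of the Myb family, rose by 4.44, Vxn by 3.39 and the retinoid-binding protein gene Rbp7 by 3.21. Phgdh and Psat1 catalyse successive steps of serine synthesis, and fell by 4.10 ± 0.23 (adjusted p = 2.24e-05) and decreased by 3.66 ± 0.37 (adjusted p = 0.00126). Asns fell by 3.54 ± 0.13 (adjusted p = 2.14e-06), from 697 ± 59.9 to 45.5 ± 9.76. The hepatic hormone gene Fgf21 fell by 3.24 ± 0.66 and the protease inhibitor A2m fell by 2.94 ± 0.49. In each of these genes all 3 hepatitis arrays lay on one side of all 3 controls.

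Of 20 p53 targets measured, 8 rose and 1 fell (9 and 2 adjusted over the list alone), and camera placed the list higher (adjusted p = 5.69e-08, or adjusted p = 0.43 with an estimated correlation). Ccng1 rose by 2.77, Phlda3 by 2.58 and the kinase gene Plk2 by 1.69, while Ddit4, named after its value was seen, fell by 1.02. All 16 measured genes of fatty acid synthesis had a list median of -1.83, with 6 fallen (11 adjusted over the list alone, camera adjusted p = 1.07e-09, or adjusted p = 0.43 with an estimated correlation). Malic enzyme (Me1) fell by 2.40, with liver pyruvate kinase (Pklr) at -2.39, fatty acid synthase (Fasn) at -2.30 and the elongase Elovl6 at -2.03. Cholesterol synthesis had a median of -1.26 over 18 genes, of which 4 fell (15 adjusted over the list alone, camera adjusted p = 9.62e-11, or adjusted p = 0.438 with an estimated correlation). Its fallen members were Mvd at -1.28, Stard4 at -0.94, Mvk at -0.85 and the transcription factor gene Srebf2 at -0.84. Fatty acid oxidation shifted up, with 3 of 24 genes risen (7 up and 1 down adjusted over the list alone, camera adjusted p = 0.00311, or adjusted p = 0.73 with an estimated correlation), namely Eci1 at 1.47, Acadl at 0.86 and Eci2 at 0.84.

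In the list named for the unfolded protein response the 3 fallen genes of 17, also 3 adjusted over the list alone, were Asns, Trib3 and Atf4, which are known for the response to amino acid shortage. Camera gave the list an adjusted p = 0.00445, or adjusted p = 0.656 with an estimated correlation. Atf4 encodes its transcription factor and fell by 0.76, and Trib3 fell by 1.31. Gluconeogenesis and glycogen genes shifted down, with 3 of 10 fallen (3 adjusted over the list alone), led by the glucose-6-phosphate transporter Slc37a4 at -1.31 (camera adjusted p = 0.00633, or adjusted p = 0.592 with an estimated correlation). The gluconeogenesis mean was 10.27 on hepatitis replicate 3, within the control range of 10.26 to 10.41, and 9.69 and 9.64 on the other hepatitis arrays. Among 16 liver transcription factors 4 fell (5 adjusted over the list alone), namely Nr0b2 at -2.80, Cebpa at -1.65, Cebpb at -0.74 and Nr5a2 at -0.43 (camera adjusted p = 0.0378, or adjusted p = 0.704 with an estimated correlation). Bile acid synthesis and transport was placed lower, with 1 of 19 fallen (1 adjusted over the list alone), the sterol exporter gene Abcg5 at -1.79 (camera adjusted p = 0.0364, or adjusted p = 0.798 with an estimated correlation).

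Several lists of other cell types shifted up by small amounts. B and plasma cell genes had 2 of 7 risen (4 adjusted over the list alone), the plasma cell genes Jchain at 2.05 and Mzb1 at 0.83 (camera adjusted p = 0.00217, or adjusted p = 0.43 with an estimated correlation). In the neutrophil and mast cell list 2 of 12 rose, and 2 adjusted over the list alone, the calprotectin genes S100a9 at 2.33 and S100a8 at 2.30 (camera adjusted p = 0.0342, or adjusted p = 0.43 with an estimated correlation). Stellate cell genes had 2 of 16 risen (2 adjusted over the list alone), the pericyte gene Rgs5 at 1.75 and Cygb at 0.91 (camera adjusted p = 0.0154, or adjusted p = 0.446 with an estimated correlation). The macrophage list had a median of 0.38 and was placed higher, with 0 of 18 risen and 1 fallen (0 and 1 adjusted over the list alone), the endotoxin receptor gene Cd14 at -1.34 (camera adjusted p = 0.0244, or adjusted p = 0.798 with an estimated correlation). Control replicate 3 stood apart, with a macrophage list mean of 9.31 (log2) against 8.27 and 8.11 on the other controls and 8.78 to 9.14 in hepatitis. Its MHC class II mean was 9.85, against 7.72 and 7.55 on the other controls and 8.84 to 9.54 in hepatitis. The cholangiocyte mean was 6.86 on hepatitis replicate 1, 5.52 and 5.56 on the other hepatitis arrays and 5.3 to 5.36 in control. Cholangiocyte genes had a median of 0.65 and MHC class II genes 0.94, with 0 of 11 and 0 of 9 past the threshold, also 0 adjusted over each list alone (camera adjusted p = 0.0311 and 0.0216, or adjusted p = 0.823 and 0.798 with an estimated correlation). The proliferation mean was 6.48 on control replicate 3, between 6.9 on hepatitis replicate 1 and 6.37 and 6.15 on the others, against 5.98 and 6.17 on the other controls. Cell proliferation had a median of 0.20 with 1 of 38 risen (1 adjusted over the list alone), thymidylate synthase (Tyms) at 1.09 (camera adjusted p = 0.00932, or adjusted p = 0.875 with an estimated correlation). Erythroid genes shifted down, with 1 of 7 fallen (5 adjusted over the list alone), the haem synthesis gene Alas2 at -1.77 (camera adjusted p = 0.000429, or adjusted p = 0.43 with an estimated correlation).

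The skeletal muscle list was placed lower with 0 of 12 genes past the threshold, also 0 adjusted over the list alone, and a median of -0.83. Camera gave the list an adjusted p = 0.0154, or adjusted p = 0.798 with an estimated correlation. On control replicate 2 alone muscle actin (Acta1) had an intensity of 1200, against 7.21 and 17 on the other controls. The muscle list call ended without control replicate 2 (adjusted p = 0.221) or HCC replicate 1 (0.0551), and its direction turned when the dimmest 30% of genes were left out (adjusted p = 0.345). Female-biased liver genes shifted up, with 2 of 11 risen (4 up and 1 down adjusted over the list alone), Cyp3a9 at 2.91 and the transcription factor gene Cux2 at 0.95 (camera adjusted p = 0.0218, or adjusted p = 0.781 with an estimated correlation).

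The remaining lists were not called by camera in hepatitis. Their genes past the threshold included the chemokine gene Ccl21 at 1.61, the ubiquitin-like interferon-induced gene Isg15 at 0.86, the matrix metalloprotease inhibitor Timp2 at 1.15, and Fabp4, a lipid-binding protein of adipocytes that macrophages and endothelium also express, at 1.84. Of 11 male-biased liver genes 3 rose and 0 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.322). Among the 3 were Mup5 at 2.06 and Dhrs7 at 0.83. Serine dehydratase (Sds) rose by 3.0 and placental glutathione transferase (Gstp1) by 2.04, while Cyp1a1 fell by 2.14, with the imprinted RNA gene H19 at -2.84 and Cela1, of the pancreatic acinar list, at -2.75. Hepatocyte plasma protein genes had a median of -0.03, with 0 of 22 past the threshold in limma (0 adjusted over the list alone), and albumin (Alb) had a difference of -0.04. Alb, at 14800 in control and 14100 to 14600 in the other groups, lay near the arrays' highest values (13675 to 15006), so its differences are not informative in any comparison. Afp had a difference of 0.83, Gpc3 0.60, Ggt1 0.50, Col1a1 -0.39, Acta2 0.39, Krt19 0.49, Mki67 0.16, Cyp7a1 -1.16 and Cyp2c11 -1.83, none of them past the threshold.

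The hepatitis count of 568 genes was 204 without control replicate 1, 180 without control replicate 2, 234 without hepatitis replicate 1, 1078 without HCC replicate 1 and 1001 without HCC replicate 2. Of 69 named genes past the threshold 29 stayed so whichever array was left out. Calls that ended without an array, with the camera adjusted p left, were cholangiocytes (control 1, 0.0522; control 3, 0.0506; hepatitis 1, 0.283), macrophages (control 1, 0.18; control 2, 0.308; hepatitis 1, 0.0671; hepatitis 2, 0.0697). Others were neutrophils (control 1, 0.127; hepatitis 2, 0.0697; HCC 1, 0.0681; HCC 2, 0.0659; HCC 3, 0.0599), proliferation (control 1, 0.169; hepatitis 1, 0.475), MHC class II (control 1, 0.183; control 2, 0.236; hepatitis 1, 0.0587). Also lost were transcription factors (control 1, 0.0827; hepatitis 1, 0.0978; HCC 1, 0.0518; HCC 3, 0.0601), bile acids (control 2, 0.079; hepatitis 1, 0.127), female-biased genes (hepatitis 3, 0.0536), and fatty acid oxidation (hepatitis 3, 0.0952). With the dimmest 30% of genes left out the calls of cholangiocytes (0.0559), macrophages (0.0511), transcription factors (0.0823) and female-biased genes (0.139) ended, and with the mean of all probe sets of a gene that of stellate cells (0.0763).

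The second comparison asked what distinguished the cirrhosis stage from control. Of 25 genes of the NRF2 and phase II group, which detoxify electrophiles, 8 rose and 0 fell (adjusted p = 0.43 with an estimated correlation). Among them Gstp1 rose by 4.03 ± 0.44 (log2, SE, n = 3 per group; limma adjusted p = 0.00356), from an intensity of 345 ± 12.1 to 5900 ± 887 (SD). Of 22 interferon response genes 7 rose, and of 11 male-biased liver genes 2 rose (adjusted p = 0.43 and 0.446 with an estimated correlation). In hepatitis 3 of these 11 male-biased genes had already risen, although camera did not call the list there (adjusted p = 0.322). Of 33 extracellular matrix genes 0 rose and 1 fell, and camera did not call the list (adjusted p = 0.697). In limma's test 219 genes were higher and 256 lower, of which 64 and 66 changed at least 2-fold.

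Obp3, a lipocalin of the male-biased list, had the largest rise, at 6.93 ± 0.61 (adjusted p = 0.000877), from 11 ± 1.37 to 3510 ± 1410 (SD, n = 3; limma test). Dhrs7l1, of the short-chain dehydrogenase family, rose by 4.15, Cyp3a9 by 3.77 and the aldo-keto reductase gene Akr1b8 by 3.67. Asns fell by 3.20 ± 0.13 (adjusted p = 5.8e-06), with the zinc finger gene Zfp354a at -3.18, Fgf21 at -3.13 and Cela1 at -2.79. Phgdh fell by 2.98 ± 0.23 (limma adjusted p = 0.000502). All 3 cirrhosis arrays lay on one side of all 3 controls in each of these genes.

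Of 25 NRF2 and phase II genes 8 rose and 0 fell (12 up adjusted over the list alone, camera adjusted p = 1.72e-07, or adjusted p = 0.43 with an estimated correlation). Beside Gstp1 and Akr1b8, the aldehyde dehydrogenase Aldh3a1 rose by 2.20 and sulfiredoxin (Srxn1) by 1.71. The interferon response had 7 of 22 risen (9 adjusted over the list alone), with Oas1a at 1.74, Mx2 at 1.69, Isg15 at 1.51 and Usp18 at 1.33 (camera adjusted p = 6.61e-08, or adjusted p = 0.43 with an estimated correlation). Male-biased liver genes had a median of 0.80, with 2 of 11 risen (5 adjusted over the list alone), Obp3 and the urinary protein gene Mup5 at 3.59 (camera adjusted p = 1.52e-05, or adjusted p = 0.446 with an estimated correlation). In the neutrophil and mast cell list the 3 risen of 12 (5 adjusted over the list alone) were mast cell genes, Mcpt1 at 1.75, Cpa3 at 1.53 and Fcer1a at 0.58 (camera adjusted p = 0.00189, or adjusted p = 0.43 with an estimated correlation). Control replicate 3 stood apart here too, with an interferon list mean of 7.69 (log2) against 7.18 and 7.07 on the other controls and 7.85 to 8.08 in cirrhosis. Its mean of cytokines and chemokines was 6.57, within the 6.56 to 6.68 of cirrhosis, against 6.36 and 6.18. Cytokines and chemokines had 2 of 24 risen (4 adjusted over the list alone), Ccl21 at 1.98 and the NF-kappaB feedback gene Tnfaip3 at 0.78 (camera adjusted p = 0.00835, or adjusted p = 0.73 with an estimated correlation). B and plasma cells had 1 of 7 risen (2 adjusted over the list alone), Jchain at 2.58 (camera adjusted p = 0.0113, or adjusted p = 0.43 with an estimated correlation). Cholangiocyte genes had a median of 0.61, with 0 of 11 past the threshold, also 0 adjusted over the list alone (camera adjusted p = 0.0236, or adjusted p = 0.823 with an estimated correlation).

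Erythroid genes fell in 4 of 7 (5 adjusted over the list alone), with Alas2 at -1.81, beta globin (Hbb) at -1.79, the band 3 anion exchanger Slc4a1 at -1.31 and Ahsp at -0.95. Camera gave the list an adjusted p = 1.79e-05, or adjusted p = 0.43 with an estimated correlation. Gluconeogenesis and glycogen genes fell in 4 of 10 (6 adjusted over the list alone), with Igfbp1 at -2.27, Slc37a4 at -1.21, glycogen phosphorylase (Pygl) at -0.85 and pyruvate carboxylase (Pc) at -0.61 (camera adjusted p = 2.8e-05, or adjusted p = 0.43 with an estimated correlation). Fatty acid synthesis had 3 of 16 fallen (5 adjusted over the list alone), Me1 at -1.46, Pklr at -1.27 and acetyl-CoA carboxylase (Acaca) at -0.92 (camera adjusted p = 0.00633, or adjusted p = 0.781 with an estimated correlation). In the unfolded protein response list Asns and Trib3, at -1.06, were the 2 fallen of 17 (3 adjusted over the list alone, camera adjusted p = 0.03, or adjusted p = 0.781 with an estimated correlation). Bile acid synthesis and transport had 1 of 19 fallen (3 adjusted over the list alone), Abcg5 at -1.70 (camera adjusted p = 0.0362, or adjusted p = 0.798 with an estimated correlation). The muscle list again had 0 of 12 past the threshold (0 adjusted over the list alone) and a median of -0.84, beside the muscle gene signal on control replicate 2 (camera adjusted p = 0.0154, or adjusted p = 0.798 with an estimated correlation). Its direction turned when the dimmest 30% of genes were left out (adjusted p = 0.362).

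Among 33 extracellular matrix genes 0 rose and 1 fell (2 up and 1 down adjusted over the list alone), the collagen gene Col5a1 at -0.83, and the list median was 0.01 (camera adjusted p = 0.697). Collagen type I (Col1a1) had a difference of -0.58 ± 0.35 and smooth muscle actin (Acta2), the myofibroblast marker, 0.11 ± 0.15, with limma adjusted p of 0.49 and 0.843. Of 16 stellate cell genes 1 rose, Cygb at 0.88 (2 adjusted over the list alone, camera adjusted p = 0.174). The p53 target list had 2 risen and 1 fallen of 20 (6 and 3 adjusted over the list alone), with Phlda3 at 0.67, the DNA repair gene Xpc at 0.56 and Ddit4 at -1.20 (camera adjusted p = 0.484), and Cdkn1a had a difference of 0.36. Sinusoidal endothelium had 1 fallen of 12, Stab1 at -0.90 (1 adjusted over the list alone, camera adjusted p = 0.952). Other differences not past the threshold were Afp 0.84, Gpc3 0.71, Ggt1 1.52, Krt19 0.81, Mki67 -0.52, Alb -0.03, Cyp7a1 -1.71 and Cyp2c11 0.70.

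The cirrhosis count of 475 genes was 136, 121 and 260 without control replicates 1, 2 and 3, then 119, 101 and 97 without cirrhosis replicates 1, 2 and 3, and 886, 791 and 734 without HCC replicates 1, 2 and 3. Averaging the 3 cirrhosis arrays, which were very alike, to 1 leaves each fold as it was and takes the spread from the other groups alone. The mean then counts as 1 array, so the standard error is larger by construction at the same spread. That fit therefore does not show how far the calls rest on the small cirrhosis spread. Of 53 named genes past the threshold 16 stayed so whichever array was left out. Calls that ended, with the camera adjusted p left, were the unfolded protein response without control 1 (0.0692), HCC 1 (0.0552) or HCC 3 (0.0519) and with the dimmest 30% of genes left out (0.0633). Others were muscle without control 2 (0.397) or HCC 1 (0.0552), bile acids without control 2 (0.079) or cirrhosis 2 (0.065), and cytokines without control 2 (0.122).

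The third comparison asked what distinguished HCC tissue from control liver. Insulin-like growth factor 2 (Igf2), a fetal growth factor, had the largest rise at 6.80 ± 0.49 (log2, SE, n = 3 per group; limma adjusted p = 2.56e-05). Of 38 proliferation genes 34 rose, and of 18 oncofetal and HCC markers 8 rose (adjusted p = 0.656 and 0.496 with an estimated correlation). Of 19 bile acid genes 17 fell, and of 19 xenobiotic oxidases 16 fell and 1 rose (adjusted p = 0.43 and 0.438 with an estimated correlation). Fatty acid oxidation fell in 22 of 24 genes and amino acid catabolism in 22 of 25 (adjusted p = 0.43 and 0.437 with an estimated correlation). Limma called 2840 genes higher and 2661 lower, of which 697 and 1009 changed at least 2-fold. In simulated data this fit called 239 unchanged genes, more than the changed genes it recovered. The HCC calls and the genes counted as risen or fallen may thus hold an unknown share of false calls. A fit of only these 2 groups called 3198 genes.

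Igf2 went from an intensity of 44.1 ± 3.05 to 8320 ± 5390 (SD, n = 3), and 1 of its 4 probe sets was past the threshold when all probe sets were tested. The cadherin gene Cdh22 rose by 6.25 ± 0.84 (adjusted p = 0.000438), Akr1b8 by 5.35 ± 0.52 (adjusted p = 8.64e-05), the imprinted RNA gene Meg3 by 4.90 and Afp by 4.72 ± 0.82 (adjusted p = 0.00168; limma test). Fabp7, a fatty acid binding protein gene, fell by 4.55, and the vasopressin receptor gene Avpr1a fell by 4.49 ± 0.25 (adjusted p = 1.1e-05). Ust5r was at -4.44, the glutathione transferase Gstp3 at -4.39 and the carbonic anhydrase gene Car3 at -4.28. In each of these all 3 HCC arrays lay on one side of all 3 controls. Gstp1 rose by 4.57, Ggt1 by 2.18, Gpc3 by 2.62, Col1a1 by 1.37, Acta2 by 0.65, Mki67 by 2.34 and Cdkn1a by 0.91. Cyp7a1, which catalyses the rate-limiting step of bile acid synthesis, fell by 4.12, and the male-specific Cyp2c11 fell by 3.4. The cholangiocyte keratin gene Krt19 had a difference of 2.35, not past the threshold, although it passed it without HCC replicate 2, at 3.56. Alb, near the top of the intensity range, had a difference of -0.08.

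Of 38 proliferation genes 34 rose and 0 fell (36 up adjusted over the list alone), with Ccna2 at 2.68, Cdc20 at 2.46 and Cdk1 at 2.07 beside Mki67. Camera gave the list an adjusted p = 3.49e-10, or adjusted p = 0.656 with an estimated correlation. Oncofetal and HCC markers rose in 8 of 18 (8 adjusted over the list alone), with the transcription factor gene Sox4 at 3.16 and H19 at 2.73 after Igf2 and Afp (camera adjusted p = 0.00293, or adjusted p = 0.496 with an estimated correlation). In the NRF2 and phase II list 17 of 25 rose and 2 fell (17 and 2 adjusted over the list alone), with Srxn1 at 2.73 and Aldh1a1 at -2.32 (camera adjusted p = 0.000286, or adjusted p = 0.496 with an estimated correlation). The interferon response had 8 of 22 risen (8 adjusted over the list alone), among them Isg15 at 2.58, Oasl at 1.95, Mx1 at 1.53 and Usp18 at 1.52 (camera adjusted p = 0.00389, or adjusted p = 0.656 with an estimated correlation). Cholangiocyte genes had a median of 1.66 and 3 of 11 risen (1 adjusted over the list alone), Epcam at 2.26, Sctr at 1.84 and Krt7 at 1.66, with list means of 8.14, 5.85 and 6.4 on HCC replicates 1, 2 and 3 (camera adjusted p = 0.0148, or adjusted p = 0.798 with an estimated correlation).

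Fatty acid oxidation fell in 22 of 24 genes (22 adjusted over the list alone), with Cyp4a1 at -3.91, Ehhadh at -3.53, Cyp4a3 at -3.24 and Bdh1 at -2.48 (camera adjusted p = 2.95e-12, or adjusted p = 0.43 with an estimated correlation). The urea cycle and amino acid catabolism list fell in 22 of 25 (23 adjusted over the list alone), with the methionine cycle genes Gnmt at -4.24, Bhmt at -3.73 and Cbs at -2.88, and Agxt at -3.44 (camera adjusted p = 4.37e-10, or adjusted p = 0.437 with an estimated correlation). Bile acid genes fell in 17 of 19 (17 adjusted over the list alone), with Cyp8b1 at -4.24 and the uptake transporters Slc10a1 at -3.87 and Slco1a4 at -3.61 (camera adjusted p = 1.5e-08, or adjusted p = 0.43 with an estimated correlation). Xenobiotic oxidases fell in 16 of 19 and rose in 1 (17 and 1 adjusted over the list alone), with Cyp1a2 at -4.21, Cyp2e1 at -3.55, Cyp2a1 at -3.23 and Cyp3a23-3a1 at -2.92 (camera adjusted p = 5.67e-07, or adjusted p = 0.438 with an estimated correlation). Gluconeogenesis and glycogen genes fell in 9 of 10 (9 adjusted over the list alone), with Fbp1 at -3.18, Slc37a4 at -2.48, Khk at -2.41 and Pck1 at -2.32 (camera adjusted p = 6.29e-06, or adjusted p = 0.43 with an estimated correlation).

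Plasma protein genes fell in 17 of 22 (19 down and 1 up adjusted over the list alone), with the growth hormone receptor Ghr at -2.43, Igf1 at -1.97, Vtn at -1.76 and Fetub at -1.64. Camera gave the list an adjusted p = 1.08e-05, or adjusted p = 0.746 with an estimated correlation. Among liver transcription factors 10 of 16 fell (10 adjusted over the list alone), with Nr0b2 at -3.79, Nr1i3 at -2.05, the bile acid receptor Nr1h4 at -1.65 and Cebpa at -1.55 (camera adjusted p = 0.000932, or adjusted p = 0.438 with an estimated correlation). Pericentral and Wnt target genes fell in 9 of 13 and rose in 1 (9 and 1 adjusted over the list alone), with Gulo at -4.01 and Lect2 at -3.96 (camera adjusted p = 0.000952, or adjusted p = 0.437 with an estimated correlation). Male-biased genes fell in 8 of 11 and rose in 1 (8 and 1 adjusted over the list alone), with Cyp3a18 at -3.27, Sult1e1 at -2.86 and Cyp2c13 at -2.61 (camera adjusted p = 0.00287, or adjusted p = 0.688 with an estimated correlation). Acute phase proteins fell in 9 of 17 (10 adjusted over the list alone), with Crp at -3.77 and Orm1 at -1.70 (camera adjusted p = 0.00476, or adjusted p = 0.688 with an estimated correlation). Cholesterol synthesis fell in 7 of 18 (11 adjusted over the list alone), with Msmo1 at -1.89 and Tm7sf2 at -1.87 (camera adjusted p = 0.000644, or adjusted p = 0.798 with an estimated correlation). Fatty acid synthesis fell in 8 of 16 (8 adjusted over the list alone), with Thrsp at -4.02, the desaturase genes Scd at -3.89 and Fads2 at -3.21, and Pklr at -2.51 (camera adjusted p = 0.0148, or adjusted p = 0.798 with an estimated correlation). Its call ended with quantile normalization (adjusted p = 0.0517).

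Sinusoidal endothelium fell in 11 of 12 (11 adjusted over the list alone), with the scavenger receptor Stab2 at -3.53, Kdr at -2.06, Fcgr2b at -1.70 and Lyve1 at -1.59 (camera adjusted p = 7.52e-06, or adjusted p = 0.43 with an estimated correlation). Macrophage genes fell in 7 of 18 and rose in 1 (7 and 1 adjusted over the list alone), with the Kupffer cell genes Clec4f at -2.43 and Cd5l at -2.33, C1qb at -2.04 and Cd163 at -1.96 (camera adjusted p = 0.0218, or adjusted p = 0.798 with an estimated correlation). Erythroid genes fell in 4 of 7 (4 adjusted over the list alone), with Hbb at -3.48, Alas2 at -2.06 and Slc4a1 at -1.50 (camera adjusted p = 0.00458, or adjusted p = 0.446 with an estimated correlation). The matrix mean was 8.37 on HCC replicate 1, 7.67 and 7.73 on the other HCC arrays and 7.28 to 7.52 in control. In the matrix list 12 of 33 rose and 3 fell (12 and 3 adjusted over the list alone), with lumican (Lum) at 2.41, decorin (Dcn) at 1.96, Loxl1 at 1.81 and Postn at 1.75. Camera did not call the matrix list (adjusted p = 0.0598). Of 16 stellate cell genes 5 rose and 3 fell (5 and 3 adjusted over the list alone), with vimentin (Vim) at 1.29 and the vitamin A storage enzyme Lrat at -2.74 (camera adjusted p = 0.567).

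Other uncalled lists held genes past the threshold in both directions. Of 20 p53 targets 2 rose, Cdkn1a among them, and 5 fell (2 and 5 adjusted over the list alone, camera adjusted p = 0.32). Phlda3, chosen after its value was seen, was at -0.49. The T and NK cell mean was 5.85 on control replicate 3 against 5.35 and 5.37 on the other controls, and 5.94, 5.39 and 5.73 on HCC replicates 1, 2 and 3. T and NK cells had 8 of 19 risen and 1 fallen (10 and 2 adjusted over the list alone), with Cd3g at 1.60 and Ccl5 at -1.41 (camera adjusted p = 0.293). Vascular endothelium had 1 of 11 risen and 2 fallen (1 and 1 adjusted over the list alone), Aplnr at 0.34, Eng at -0.75 and Tek at -0.60 (camera adjusted p = 0.569). The glycolysis mean was 8.46 on HCC replicate 1 and 7.56 on both other HCC arrays, within the control range of 7.5 to 7.6. Glycolysis had 6 of 18 risen and 2 fallen (7 and 2 adjusted over the list alone), with Pfkp at 1.64, Aldoa at 1.49 and lactate dehydrogenase A (Ldha) at -1.33 (camera adjusted p = 0.247). The circadian clock had 3 of 16 risen and 7 fallen (3 and 7 adjusted over the list alone), with Hlf at -1.97, Dbp at -1.78 and Nr1d1 at -1.76 (camera adjusted p = 0.186). Immediate early genes had 2 of 14 risen and 3 fallen (2 and 3 adjusted over the list alone), with Klf6 at 1.85, Myc at 1.41 and Dusp1 at -2.64 (camera adjusted p = 0.945). The adipocyte list had 1 of 9 risen and 3 fallen (1 and 3 adjusted over the list alone), Fabp4 at 0.78, Cidec at -1.42, Pnpla2 at -0.89 and Cfd at -0.66 (camera adjusted p = 0.484). The pancreatic acinar list had 1 of 12 risen and 1 fallen (1 and 1 adjusted over the list alone), Cpa1 at 0.61 and Cela1 at -2.73 (camera adjusted p = 0.908). The cytokine mean was 6.9 on HCC replicate 1 and 6.34 and 6.38 on the others, within the control range of 6.18 to 6.57. Cytokines had 4 of 24 risen and 3 fallen (4 and 2 adjusted over the list alone), with Cxcl12 at -3.52 (camera adjusted p = 0.315).

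Named after their values were seen, further members past the threshold in HCC against control were Col14a1 at -1.49, Sparc at -0.69 and Spon2 at -0.68 in the matrix. Chosen likewise were Myl9 at -0.62 and Hand2 at -0.34 among stellate cell genes, the lysozyme gene Lyz2 at 1.18 among macrophage genes. So were the epoxide hydrolase gene Ephx1 at -1.50, Mup5 at 1.05, Cyp1b1 at 0.33, Tcf7 at 0.76 and Pdk1 at -0.63. Chosen the same way, Clock at 0.42, Per2 at 0.84 and Bhlhe41 at 1.06 were the risen clock genes. Pdgfrb at 0.46, Fosb at -0.21, Cxcl2 at 0.55, Tgfb2 at 0.39 and Csf1 at -0.46 were also chosen after their values were seen. By the rule named before, Tpm2 at 0.69, Cygb at 1.14, Zfp36 at -1.12, Il1a at -1.54, Cx3cl1 at 0.95 and Ccl21 at 0.72 were further members.

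HCC replicate 2 lay nearer to the livers than the other HCC arrays, and all 3 HCC arrays had larger 3' to 5' differences than the livers, beside every gene group described here. On HCC replicates 1, 2 and 3 the mean of fatty acid synthesis genes was 7.75, 9.04 and 7.48 (control 9.24 to 9.28), of plasma protein genes 11.13, 12.24 and 10.94 (control 12.53 to 12.57) and of cholesterol synthesis genes 8.46, 9.2 and 7.75 (control 9.32 to 9.72). The HCC count of 5501 genes ranged from 4179 to 6332 when each of the 12 arrays was left out, and was 3966 with the Gapdh 3' minus 5' difference as a covariate, 2932 of them shared. Of 139 named genes past the threshold 113 stayed so whichever array was left out. Calls that ended, with the camera adjusted p left, were macrophages without control 3 (0.269) or HCC 2 (0.0718), cholangiocytes without HCC 1 (0.0504) and fatty acid synthesis without HCC 1 (0.0822).

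**Figure D3:**
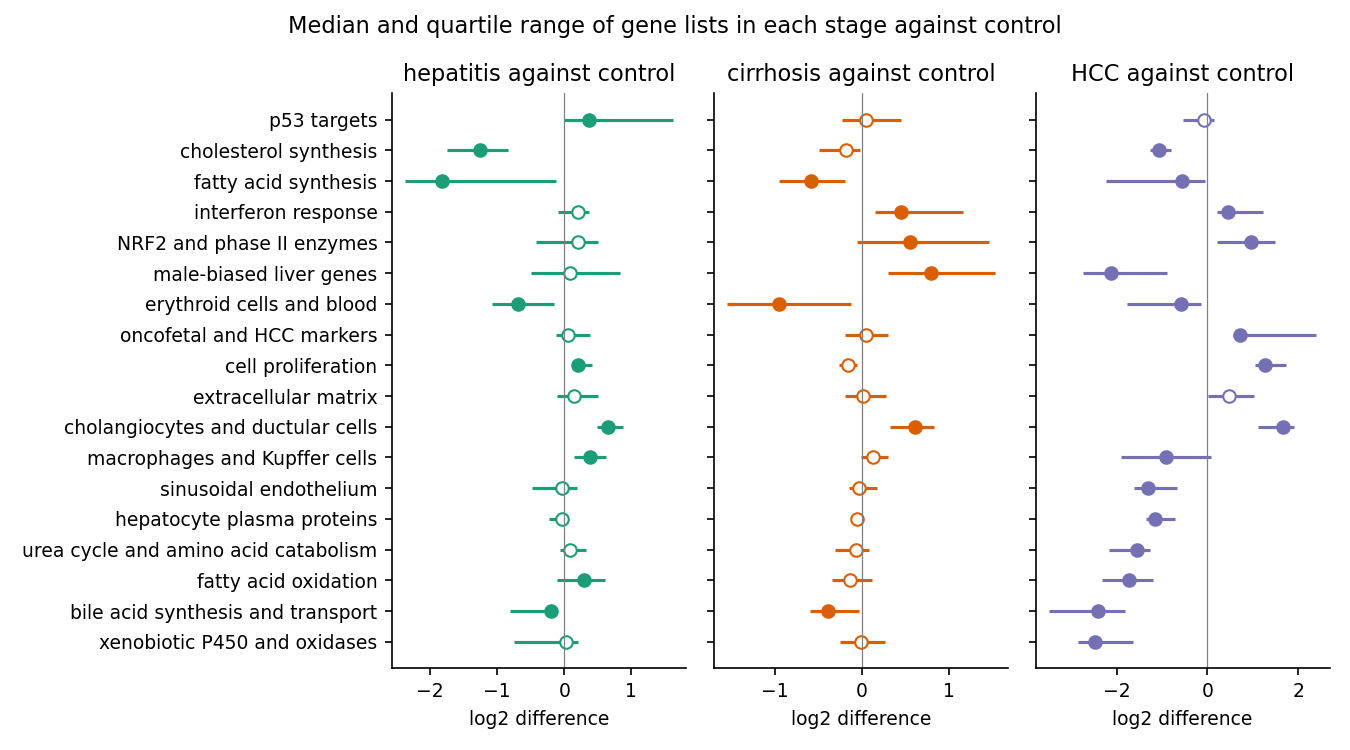
Markers show the median log2 difference of a gene list from control and bars its quartile range, for hepatitis, cirrhosis and HCC, with filled markers for lists called by camera at a preset correlation. Fatty acid oxidation has a median of -1.73 in HCC and 0.29 in hepatitis.

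**Figure D4:**
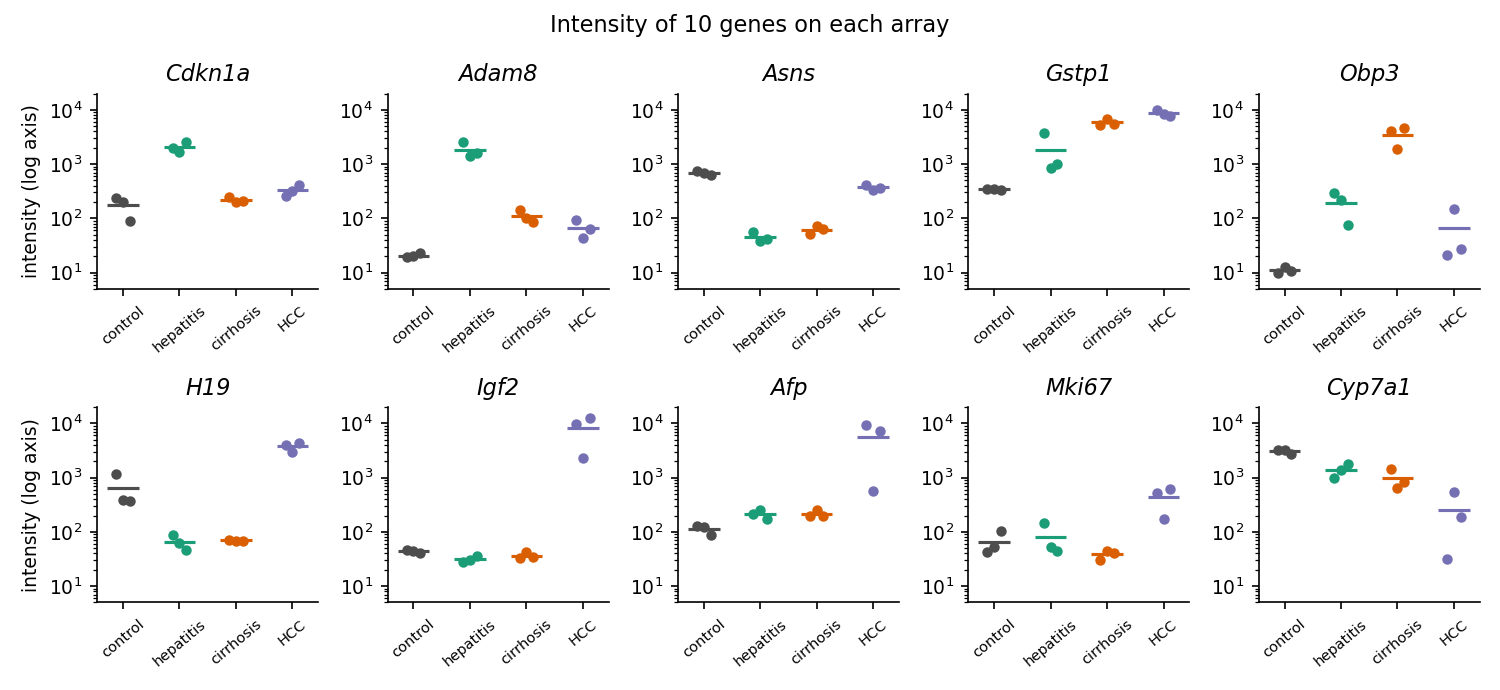
Points show the intensity of 10 genes on each of the 12 arrays, on a log axis, and horizontal lines the group means. Obp3 has means of 11 in control and 3510 in cirrhosis, and Igf2 has means of 44.1 in control and 8320 in HCC.

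The stages were next compared with each other. If the weeks count from the start of DEN treatment, week 5 lies within the 10 weeks of injections and weeks 13 to 14 lie after them. Whichever way they count, stage and time since DEN cannot be told apart. From hepatitis to cirrhosis 7 of 20 p53 targets fell (adjusted p = 0.43 with an estimated correlation). Adam8 fell by 3.87 ± 0.26 (log2, SE, n = 3 per group; limma adjusted p = 0.000236) and Cdkn1a fell by 3.17 ± 0.31 (adjusted p = 0.00201). Higher in cirrhosis were 3 of 25 NRF2 and phase II genes, 3 of 22 interferon response genes and 3 of 11 male-biased genes (adjusted p = 0.43, 0.43 and 0.446 with an estimated correlation). Limma called 56 genes higher and 80 lower, of which 23 and 35 changed at least 2-fold. Obp3 rose by 4.15, Stac3 by 2.56, Dhrs7l1 by 2.55, Ddit4l by 2.23 and the protease inhibitor Mug1 by 2.14. Vxn was at -2.75, Rbp7 at -2.76 and the DNA end-joining gene Nhej1 at -2.53.

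Between hepatitis and cirrhosis 7 of 20 p53 targets fell (11 down and 1 up adjusted over the list alone), with Ccng1 at -1.96, Phlda3 at -1.90 and Mdm2 at -1.41. Camera gave the list an adjusted p = 2.95e-12, or adjusted p = 0.43 with an estimated correlation. NRF2 and phase II genes rose in 3 of 25 (13 up and 1 down adjusted over the list alone), Aldh3a1 at 2.0, Akr7a3 at 1.89 and Gclm at 1.44 (camera adjusted p = 3.35e-09, or adjusted p = 0.43 with an estimated correlation). The interferon response rose in 3 of 22 (9 adjusted over the list alone), Mx2 at 1.44, Usp18 at 1.24 and Isg15 at 0.65 (camera adjusted p = 2.5e-08, or adjusted p = 0.43 with an estimated correlation). Male-biased genes rose in 3 of 11 (4 adjusted over the list alone), Obp3, Stac3 and Mup5 at 1.53 (camera adjusted p = 1.96e-05, or adjusted p = 0.446 with an estimated correlation). Cholesterol synthesis had a median of 0.92 and fatty acid synthesis 1.06, with 0 of 18 and 0 of 16 past the threshold and 10 and 8 up adjusted over the list alone (camera adjusted p = 9.23e-11 and 6.71e-08, or adjusted p = 0.438 and 0.437 with an estimated correlation). Fatty acid oxidation had 2 of 24 fallen (8 down and 1 up adjusted over the list alone), Eci1 at -1.34 and Hadhb at -0.89 (camera adjusted p = 6.56e-06, or adjusted p = 0.446 with an estimated correlation). Proliferation had 1 of 38 fallen (1 adjusted over the list alone), Tyms at -1.05 (camera adjusted p = 1.75e-07, or adjusted p = 0.761 with an estimated correlation). Liver transcription factors had a median of 0.17 and 0 of 16 past the threshold (0 adjusted over the list alone, camera adjusted p = 0.0479, or adjusted p = 0.73 with an estimated correlation).

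The count of 136 genes between hepatitis and cirrhosis was 86 and 83 without control replicates 1 and 2, 70, 213 and 67 without hepatitis replicates 1, 2 and 3, and 44, 46 and 39 without cirrhosis replicates 1, 2 and 3. It was 269, 333 and 223 without HCC replicates 1, 2 and 3. Averaging the cirrhosis arrays to 1 left the folds unchanged. Their mean then counts as 1 array, with a larger standard error by construction and the spread from the other groups alone. Of 26 named genes past the threshold 10 stayed so whichever array was left out. The transcription factor call ended without hepatitis 1 (camera adjusted p = 0.264), hepatitis 2 (0.0594), cirrhosis 2 (0.114), HCC 1 (0.0583) or HCC 3 (0.0553), and with quantile normalization (0.0517).

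HCC tissue was compared with cirrhosis to ask what differed between the tumour and the preceding stage. Igf2 rose by 7.00 ± 0.49 (log2, SE, n = 3 per group; limma adjusted p = 2.2e-05), Cdh22 by 6.03, H19 by 5.47 ± 0.38 (adjusted p = 2.16e-05), Meg3 by 4.72 and Afp by 3.88. All 11 male-biased genes fell (adjusted p = 0.43 with an estimated correlation), and Obp3 fell by 5.69 ± 0.61 (limma adjusted p = 0.000125). Dhrs7l1 was at -4.92, Gstp3 at -4.53, Cyp2c7 at -4.42 and Crp at -4.26. Limma called 2754 genes higher and 2508 lower, of which 700 and 968 changed at least 2-fold. In simulated data this fit called 241 unchanged genes, more than the changed genes it recovered, so the same limit holds here. A fit of only these 2 groups called 3492 genes.

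Against cirrhosis 36 of 38 proliferation genes rose (37 adjusted over the list alone), with Mki67 at 2.86 and Mcm4 at 2.34 (camera adjusted p = 1.46e-11, or adjusted p = 0.592 with an estimated correlation). Oncofetal markers rose in 7 of 18 and fell in 2 (7 and 2 adjusted over the list alone), with Aldh3a1 at -1.63 and Tert, named after its value was seen, at -0.20 (camera adjusted p = 0.0216, or adjusted p = 0.688 with an estimated correlation). All 11 male-biased genes fell (11 adjusted over the list alone), with Cyp2c11 at -4.10, Sult1e1 at -4.06 and Cyp3a18 at -3.36 (camera adjusted p = 8.17e-08, or adjusted p = 0.43 with an estimated correlation). The female-biased mean on HCC replicate 2 was 8.16, within the cirrhosis range of 8.05 to 8.32, against 6.12 and 5.94 on the other HCC arrays. Female-biased genes fell in 4 of 11 (4 adjusted over the list alone), Cyp2c7, Cyp3a9 at -3.03, Cyp2a1 at -3.00 and Hsd17b2 at -2.08 (camera adjusted p = 0.03, or adjusted p = 0.798 with an estimated correlation). Acute phase proteins fell in 8 of 17 and rose in 1 (10 and 1 adjusted over the list alone), with A2m at 3.20 and Orm1 at -1.58 (camera adjusted p = 0.00458, or adjusted p = 0.688 with an estimated correlation). In the unfolded protein response list 5 of 17 rose and 0 fell (5 adjusted over the list alone), with Asns at 2.32, Creld2 at 1.35, Atf3 at 1.16, Hsp90b1 at 0.86 and, named after its value was seen, Ddit3 at 0.57. Camera did not call this list (adjusted p = 0.152). The mast cell genes Cpa3 at -1.76, Mcpt1 at -1.44 and Fcer1a at -0.58 were the 3 fallen of the 12 neutrophil and mast cell genes (3 adjusted over the list alone, camera adjusted p = 0.149).

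Fatty acid oxidation fell in 22 of 24 genes, with Ehhadh at -3.83, and amino acid catabolism in 22 of 25, with Sds at -3.74 (22 and 23 adjusted over each list alone, camera adjusted p = 1.46e-11 and 4.37e-10, or adjusted p = 0.43 and 0.437 with an estimated correlation). Bile acid genes fell in 15 of 19 and xenobiotic oxidases in 14 of 19, with Cyp8b1 at -4.13 and Cyp2e1 at -3.80 (15 and 14 adjusted over each list alone, camera adjusted p = 5.46e-07 and 5.67e-07, or adjusted p = 0.437 and 0.438 with an estimated correlation). Sinusoidal endothelium fell in 10 of 12 and macrophages in 9 of 18, with Stab2 at -2.52 and Clec4f at -2.62 (10 and 9 adjusted over each list alone, camera adjusted p = 1.86e-05 and 0.00616, or adjusted p = 0.43 and 0.781 with an estimated correlation). Plasma protein genes fell in 16 of 22 (18 down and 1 up adjusted over the list alone), with Ghr at -2.80 (camera adjusted p = 2.22e-05, or adjusted p = 0.772 with an estimated correlation). Liver transcription factors fell in 8 of 16 (10 adjusted over the list alone), with Onecut1 at -2.72 and Foxa1 at -1.47 (camera adjusted p = 0.00185, or adjusted p = 0.44 with an estimated correlation). Pericentral genes fell in 9 of 13 and rose in 1 (9 and 1 adjusted over the list alone), with Gulo at -3.39 and Tcf7, named after its value was seen, at 0.58 (camera adjusted p = 0.00101, or adjusted p = 0.437 with an estimated correlation). Gluconeogenesis genes fell in 7 of 10 (8 down and 1 up adjusted over the list alone), with Fbp1 at -2.89 (camera adjusted p = 0.00258, or adjusted p = 0.496 with an estimated correlation). Cholesterol synthesis fell in 4 of 18 (2 adjusted over the list alone), with Tm7sf2 at -2.16 (camera adjusted p = 0.0115, or adjusted p = 0.823 with an estimated correlation). Ldha had a difference of -1.34, which became 0.22 with the Gapdh 3' minus 5' difference as a covariate, and Aldoa of the same glycolysis list rose by 1.57.

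The count of 5262 genes between HCC and cirrhosis ranged from 4119 to 6183 when each array was left out. It was 2625 with the Gapdh difference as a covariate, 1732 of them shared, and 1679 with the cirrhosis arrays averaged to 1. Of 127 named genes past the threshold 100 stayed so whichever array was left out. Calls that ended were female-biased genes without HCC 1 (camera adjusted p = 0.133) or HCC 3 (0.0893) and cholesterol synthesis without HCC 3 (0.0935).

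The stages shared genes. Hepatitis and cirrhosis had 75 genes higher and 134 lower in both, against 4.1 and 5.4 expected from the numbers called. The 1 gene called in opposite directions, chosen after its values were seen, was Sbspon at -0.43 in hepatitis and 0.77 in cirrhosis. Hepatitis and HCC shared 105 higher and 206 lower, against 53.1 and 56.5 expected, with 54 opposite, and cirrhosis and HCC shared 92 and 150, against 43.7 and 47.9, with 64 opposite. All 3 stages shared 34 higher genes, among them Gstp1, Isg15, Adam8 and Jchain, and 92 lower genes, among them Asns, Alas2, Abcg5, Pklr and Cyp1a1. In 50 simulations of unchanged groups against the same controls the mean number of shared calls was 0, 0 and 0.02. Unchanged groups give almost no calls, so a number near 0 was fixed in advance. It does not show how much the shared controls add to the overlaps. Fold changes correlated across genes, which are not independent replicates, at 0.67, 0.39 and 0.3, against 0.5 simulated, with covariances of 0.0818, 0.103 and 0.0735 against 0.018. The simulated covariance already holds the noise that the shared controls add at the fitted spread. Whether the controls add more than that was not tested, since 3 control arrays cannot be split into 2 sets of at least 2 arrays.

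Of the 76 list calls 0 held with an estimated correlation, where 21 of 185 tests had an unadjusted p under 0.05. Fry called 54 of the 185 tests, and of the 76 camera calls it kept 48 and lost 28. Kept calls included p53 targets in hepatitis (fry adjusted p = 0.000415) and, in cirrhosis, NRF2 and phase II (0.00928) and interferon response (0.0094). Lost calls included, in hepatitis, cholangiocytes (0.475), macrophages (0.447), MHC class II (0.42) and proliferation (0.627). Limma's moderated F test called 5734 of 14217 genes as differing among the 4 groups. The overlap of hepatitis and cirrhosis, 209 genes, was 54, 47 and 136 without control replicates 1, 2 and 3, and 109 and 128 without hepatitis replicates 1 and 2. It was 58, 52 and 46 without cirrhosis replicates 1, 2 and 3, and 428, 378 and 317 without HCC replicates 1, 2 and 3. For hepatitis and HCC, 311 genes, it was 112 and 89 without control replicates 1 and 2, 124 without hepatitis replicate 1, 195, 198 and 203 without the cirrhosis replicates, and 509 and 564 without HCC replicates 1 and 2. For cirrhosis and HCC, 242 genes, it was 77, 69 and 153 without the control replicates, 65, 55 and 52 without the cirrhosis replicates, and 391 and 390 without HCC replicates 1 and 2.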

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

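In this part the tests of RNA quality, hepatocyte share and the mixture, with the bound and gene choice behind the mixture test, were chosen after the results were seen, while the muscle test, the age test and the splits were planned. Groups of 3 arrays were not tested for samples far from the others.

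The following lists and genes were picked because they were called in opposite directions against the same controls, which makes a difference between the stages nearly certain, so its test adds little. The macrophage list had a median log2 difference of 0.38 in hepatitis and -0.92 in HCC, and the median difference between these stages was -1.13 (camera adjusted p = 0.000117). Control replicate 3 stood apart in this list (mean 9.31 against 8.27 and 8.11), and without it the HCC call ended (adjusted p = 0.269), while the hepatitis call ended without control 1 (0.18), control 2 (0.308), hepatitis 1 (0.0671) or hepatitis 2 (0.0697). Male-biased liver genes had 0.8 in cirrhosis and -2.13 in HCC, differing by -2.84 (camera adjusted p = 8.17e-08), and fatty acid oxidation 0.29 in hepatitis and -1.73 in HCC, differing by -2.04 (camera adjusted p = 1.69e-16). With an estimated correlation none of these 3 differences was past the threshold (adjusted p = 0.388, 0.43 and 0.309), nor were the list calls against control (adjusted p = 0.43 or higher). Between HCC and hepatitis the log2 differences were -1.98 for Acadl, -1.66 for Cfd, -1.63 for Dhrs7, -2.61 for Eci1, -2.81 for Eci2, -2.56 for Gls2, 5.56 for H19, -3.07 for Phlda3 and 1.43 for Tkt. Between HCC and cirrhosis they were -2.64 for Eci2, 5.47 for H19 and -1.17 for Phlda3. Among 10216 probe sets without a single gene name, which the gene tests left out, 91 were higher and 119 lower in hepatitis than in control, 110 and 267 in cirrhosis, and 1277 and 886 in HCC.

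The first pattern weighed is the large number of genes, 5501, that differed between HCC and control. If it came from RNA quality, HCC replicate 1, nearest to the livers in its Gapdh 3' minus 5' difference, would shift less than replicate 3, by 0.19 times if shifts followed that difference. Over 5430 genes called without replicate 1 its shift was 0.8 times that of replicate 3 (quartiles 0.45 to 1.16), and since the lower quartile lies under the bound of 0.5, RNA quality stays open. A lower share of hepatocytes with no other change would raise all other cell types alike, yet the cholangiocyte median was 1.66 (quartiles 1.11 to 1.9) and the sinusoidal endothelium median -1.3 (-1.62 to -0.66), a difference of 2.96. These 2 lists were picked as the highest and lowest of 7 medians, and the other medians lay between -0.92 and 0.17. The cholangiocyte call ended without HCC replicate 1 (camera adjusted p = 0.0504). The sinusoidal mean was 6.3, 6.97 and 6.46 on HCC replicates 1, 2 and 3, against 7.83 to 7.87 in control. The stage itself, with age and tumour tissue confounded in it, may account for the pattern and was not tested apart from RNA quality and hepatocyte share.

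The second pattern is the position of HCC replicate 2 between the livers and the other HCC arrays. If position followed RNA quality, replicate 2 would have the smallest or largest 3' minus 5' difference of the HCC arrays, but its Gapdh value of 2.43 lay between 1.35 and 3.14 and its beta actin value of 4.28 between 3.82 and 4.85. Both lay inside by more than the largest SD of a liver group, which argues against RNA quality as measured by these control probe sets. A mixture of tissue like the other HCC arrays with liver may account for it but stays open: over 52 genes raised to like levels on those arrays the implied share had a quartile range of 0.26 around a median of 0.28 (range 0 to 1.11, with 0.06 for Afp and 0.66 for H19), which is no single share, and the bounds were set after the values were seen. A tumour of a different stage or type was not tested and stays open.

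The third pattern is the 209 genes that hepatitis and cirrhosis shared against control. Skeletal muscle in control replicate 2 may contribute: 45 shared genes were called again without that array, under the 0.5 share set beforehand for muscle as the cause. Those 45 do not need that array, but 52 were called again without control replicate 1 and 108 without control replicate 3, so this test cannot tell a loss of precision from muscle for the others. Muscle in a control would make genes lower in the stages, yet 75 of the 209 were higher, which argues against muscle for those 75. Of 12 muscle genes 0 were past the threshold in hepatitis and 0 in cirrhosis, so the muscle list itself gave no shared call. For the other lower genes muscle stays open. Younger controls may still contribute: the median of 9 genes known to decline with age was -0.07 in cirrhosis against control (quartiles -0.26 to -0.02), above the bound of -0.1 that was set before to argue against it. Because the spread reaches past that bound and 4 members lie near the floor, the rule was tightened after the value was seen. Of the 9 genes 1 fell past the threshold in cirrhosis and 0 rose. Mest, the fallen gene, was at -1.16, and at -0.97 in hepatitis, also past the threshold. Grb10 had -1.07 in cirrhosis and -0.81 in hepatitis, neither past it. The other members lay between -0.26 and 0.07 in cirrhosis and between -0.14 and 1.63 in hepatitis. The explanation by younger controls stays open. The Gapdh 3' minus 5' difference was 0.87 to 1.02 in control, 0.38 to 0.69 in hepatitis and 0.42 to 0.56 in cirrhosis. For beta actin the ranges overlapped, at 2.41 to 2.69, 2.14 to 2.54 and 2.22 to 2.42. RNA quality was not tested for the shared genes and stays open.

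Other splits of the 6 arrays of each pair of groups were too few, at 10, for a share under 0.05, and 1 split, the real one, gave as many calls in each. The real counts and the highest of the other splits, fitted with all 12 arrays, were 568 and 0 for hepatitis against control, 475 and 1 for cirrhosis against control, 5501 and 1 for HCC against control, 136 and 0 for cirrhosis against hepatitis, and 5262 and 0 for HCC against cirrhosis. Each other split of 6 arrays mixes the 2 groups and so puts their differences into the spread. Counts near 0 were thus fixed in advance and do not show how many of the real calls are false. For the F test 1 of 100 splits of the 12 arrays, the real one, gave 5734 genes, and the highest other gave 3555. That is the smallest share that 100 splits can give, so they argue against chance for that count but do not exclude it. The splits also take each array as a separate rat, which the labels do not state.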

How the results depend on the processing

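In this part the fits without the HCC arrays, with averaged cirrhosis arrays and with the Gapdh covariate were chosen after the results were seen. Counts below follow the order hepatitis, cirrhosis and HCC against control, cirrhosis against hepatitis, HCC against cirrhosis. Each array left out gave 180 to 1078, 97 to 886, 4179 to 6332, 39 to 333 and 4119 to 6183 genes, 4734 to 6606 in the F test, 69 to 84 list calls, and shared genes of 46 to 428, 89 to 564 and 52 to 391. All probe sets gave 916, 1125, 9237, 202 and 10008, and 10303 in the F test, because more features were tested. A 2-fold minimum left 180, 130, 1706, 58 and 1668 by construction. An adjusted p under 0.01 left 147, 85, 3411, 38 and 3284, 3404 in the F test, and overlaps of 34, 65 and 44, also by construction. Array weights gave 2159, 3081 and 962 for hepatitis, cirrhosis and cirrhosis against hepatitis, and the cause was not tested. Only the 2 groups compared gave 898, 2695, 3198, 446 and 3492. Without the HCC arrays the counts for hepatitis, cirrhosis and cirrhosis against hepatitis were 2119, 1756 and 827, with all 568, 475 and 136 calls among them. In these fits each fold stays as it was, so the counts changed through the estimated spread and its degrees of freedom. The median SD was 0.207 in HCC and 0.0724 to 0.104 in the other groups. The HCC arrays thus lowered the counts between the livers in the fit of all 12 arrays. Averaging the cirrhosis arrays gave 2 for cirrhosis, 0 for cirrhosis against hepatitis and 1679 for HCC against cirrhosis, by construction with each fold unchanged and fewer arrays. The Gapdh covariate gave 2625 genes for HCC against cirrhosis, and the share of calls that were higher went from 52.3% to 62.9%. For HCC against control it gave 3966, of which 2331 were higher and 1635 lower, and that share went from 51.6% to 58.8%. The covariate also turned Ldha in HCC against cirrhosis to 0.22, and the cause was not tested. Camera with an estimated correlation called 0 lists. Leaving out the dimmest 30% of genes turned the skeletal muscle list in hepatitis (adjusted p = 0.345) and cirrhosis (0.362), and the cause was not tested. Of 489 results for named genes quantile normalization left 461 the same, 27 weaker and 1 stronger, and of 76 list calls it left 74 the same and 2 weaker. Of the named genes they could test, the Gapdh covariate left 168 the same, 102 weaker and 1 stronger, and averaging the cirrhosis arrays left 117 the same and 142 weaker. The replicate block gave 309 genes for cirrhosis and 75 for cirrhosis against hepatitis, and ended the unfolded protein response call in cirrhosis (adjusted p = 0.0518), but the labels state no pairing and the arrays were not treated as paired: same-number correlations across genes were -0.26 to 0.37, with 3 of 18 over 0.1, and 7 of 12 arrays correlated best with their own number. With 33.9% to 35.8% of values under 16, changes in dim genes are understated.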

Other observations

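In this part all genes were chosen after their values were seen, and no test of a hypothesis is added. The following genes formed no list fixed beforehand. Phgdh, Psat1, Psph, Shmt2, Mthfd2, Asns, Trib3 and Fgf21 fell in hepatitis and in cirrhosis against control in limma. Atf4 fell by 0.76 in hepatitis and had a difference of -0.23 in cirrhosis, not past the threshold. Slc7a11 had -0.65 and -0.11, neither past it. Phgdh had mean intensities of 752 in control, 29.3 in hepatitis, 81.4 in cirrhosis and 776 in HCC (n = 3 each), and Psat1 had 875, 57.5, 118 and 1280. In HCC against control Phgdh differed by -0.02 (limma adjusted p = 0.968), and in HCC against cirrhosis it rose by 2.96 (adjusted p = 3.16e-05). The mitochondrial folate enzyme Mthfd2 had 193, 33.8, 41.2 and 153. Psph fell by 1.27 in hepatitis and fell by 1.19 in cirrhosis. Fgf21 stayed low in HCC, at 66.7 against 646 in control, and the cystine transporter gene Slc7a11 had 277 in HCC against 47.3.

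Imprinted genes, which also formed no such list, differed in direction in HCC. Igf2, H19 and Meg3 rose, and the growth inhibitor Cdkn1c rose by 2.11 (limma adjusted p = 0.0101). Mest fell by 1.17 and Ndn fell by 0.22, both past the threshold. Ndn lay near the floor, with intensities of 8.37 to 12.1 in control and 6.15 to 7.63 in HCC, all under 16. Dlk1 had a difference of 0.75, Grb10 0.31 and Plagl1 0.18, and these 3 were not past it. H19 had intensities of 1170, 392 and 366 on the 3 control arrays, 46.8 to 87.7 in hepatitis and 69 to 70 in cirrhosis. On control replicate 2 the muscle genes Acta1, Ckm and Tnni2 had 1200, 227 and 216, against 7.21 and 17, 8.4 and 11.5, and 19 and 25.4 on the other controls. HCC against hepatitis, compared only to test differences between stages, gave 4958 genes in limma.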
